A study of Mus musculus with 4 samples.

How the data were processed

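The study used short-oligonucleotide expression arrays for the mouse, hybridised with RNA from laser-captured intestinal epithelial cells. Per the labels' protocols and the series' design text, tissue was cut into 10 µm sections, about 16000 cells were captured per group from 4 mice (about 4000 from each), the RNA was pooled, 40 ng of total RNA was amplified in 2 rounds and hybridised to 1 array. The labels mention hematoxylin staining only for the germ-free samples. The deposited values are probe set intensities on a linear scale, which the authors made with dCHIP2004 per the series' design text. The background, model and normalization options of that step are not given in the sources used here. The table holds 45101 probe sets, of which 64 are controls. Between 1035 and 1112 of the other values per array were exactly 1, and 2 or 3 per array were lower. The deposited medians per array were 64.3 for colon wild type, 63.0 for colon germ-free, 61.7 for ileum wild type and 60.8 for ileum germ-free, and the 75th percentiles 252, 299, 247 and 240.

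These choices were made before the data were examined. The medians of the brighter 50% of probe sets were to be compared between arrays, and the values quantile-normalized if they differed by more than 0.25 log2. They differed by 0.32 (7.97 for colon wild type, 8.22 for colon germ-free, 7.95 for ileum wild type and 7.91 for ileum germ-free), so the values of the probe sets that are not controls were quantile-normalized on the log2 scale. The floor was the pooled median of all arrays, an intensity of 62.4 (5.96 log2), and lower values were set to it. A gene counted as measured in a comparison if at least 1 of the 2 arrays was above the floor. A change past 2-fold against a floored value is a lower bound. Each gene was represented by its brightest probe set, by mean log2 intensity over the arrays.

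Probe sets were named through the platform annotation, with symbols updated through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6. Of the probe sets that are not controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here; the first kind alone was used for genes, of which there were 18193 (9183 with 1 probe set). Identifiers of 34754 probe sets were in the RefSeq table, and 0 symbols differed.

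The comparisons were germ-free against wild type within each region and ileum against colon within each state. With 1 array per group they are differences of log2 values, and no p-value was computed. Genes at least 2-fold higher or lower were counted. In all, 51 gene lists were fixed beforehand: 32 of functions, 16 of cell type markers and 3 of checks (894 of 1015 list entries matched a gene here). For each function or cell type list with at least 4 measured members, the median log2 change was set against the medians of 10000 random lists of the same size, drawn from the measured genes and matched on mean expression in 20 bins. Its percentile describes these arrays, since the genes of a list are not independent, and a list stood apart below percentile 2.5 or above 97.5.

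The genes named in the text were chosen by rule. For each germ-free comparison they were the 10 genes with the largest change in each direction among those whose brighter array was above the pooled 75th percentile (an intensity of 259) and whose other measured probe sets all went the same way. For each regional comparison they were 6 such genes per direction, for both regions together 8 per direction by the smaller change, and 6 in opposite directions. The 4 members with the largest change were taken for each list described, with other members where their value was the point. The sex-linked, substrain and house-keeping genes were set aside as checks. Of these check lists, values are given below for the sex-linked genes alone, so the substrain of the mice stays unchecked here. Genes with only a clone name were skipped in naming (3 genes).

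The spread between probe sets of the same gene gives a measure of technical error within an array pair. Over genes with at least 2 bright probe sets, the SD between the brightest 2 was 0.30 log2 in colon and 0.23 in ileum for germ-free against wild type. Where the brightest probe set was past 2-fold, the next one went the same way for 45 of 59 such genes in colon and 9 of 9 in ileum. It says nothing of the spread between mice.

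The steps were tested on simulated arrays with a noise SD of 0.25 log2 per array, a 1.3-fold scale difference and 200 changed genes, in 20 simulations of the colon comparison. When all of a gene's probe sets carried the change, a log2 change of -1.5 was recovered at 2-fold for 91.7% and of 1.5 for 89.3% of genes, where the noise alone allows 92.1%. For -2.5 and 2.5 it was 100% and 99.4%. Among unchanged genes 0.405% were past 2-fold in the colon and 0.424% in a simulated ileum comparison, and 5.25% of 400 unchanged lists stood apart. When the brightest probe set alone carried the change, recovery was 89.8% at 1.5 and 99.5% at 2.5, but 81.8% at -1.5 and 84.7% at -2.5, because the choice of the brightest probe set moved to an unchanged one for 12.8 of 200 genes on average. A single simulation with 50 genes per size varied too much by chance to judge recovery, and changing the brightest probe set alone lowered that of decreases, so the test was extended to 20 simulations and to both cases.

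The alternatives were the values as deposited, scaling to a common median of the brighter 50%, a floor at the 25th or 75th percentile, no floor with 16 added before the log, the mean of a gene's probe sets, leaving out probe sets ending in _s_at or _x_at, fold thresholds of 1.5 and 3, and random lists not matched on expression. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.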

Results

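Gene expression was measured in epithelial cells cut by laser from frozen sections of the ileum and the proximal colon of C57BL/6 mice. The mice were either conventionally colonised wild type animals or germ-free animals, which live without microbes. Each of the 4 groups (colon wild type, colon germ-free, ileum wild type and ileum germ-free) had 1 array, hybridised with RNA pooled from about 4000 captured cells of each of 4 mice. The comparisons asked which epithelial transcripts differ when microbes are absent, in each gut region, and how the regions differ in either state. With 1 array per group no difference below has a replicate check, no test within a region or state was possible, and the number of arrays limits the precision. Values are quantile-normalized intensities, except those of the control probe sets, which are as deposited. A gene below the floor intensity of 62.4 on 1 of the compared arrays is given an "at least" fold.

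The colon and ileum arrays of the same status were less alike than the arrays of the same region. Across probe sets above the floor on at least 1 array, the log2 values correlated at r = 0.951 between the colon arrays, 0.975 between the ileum arrays and 0.886 between the wild type colon and ileum arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were above the floor on all 4 arrays (Eif2s3y at 1813, 2038, 1551 and 1628 in the order colon wild type, colon germ-free, ileum wild type, ileum germ-free). The X-inactivation transcript Xist stayed between 46.6 and 68.7, near the floor. Some control probe sets differed with the germ-free state in both regions, in the values as deposited. The hybridization spikes, added controls, had a median log2 change of 0.19 in colon and -0.31 in ileum, against which the values below should be read. The median of the 3 probe sets for 18S ribosomal RNA was lower on the germ-free array by a log2 change of -1.23 in colon and -0.93 in ileum. The 5' signal of the Gapdh control relative to its 3' signal shifted by -0.48 in colon and -1.10 in ileum, that of Actb by -0.12 and -1.20 and that of pyruvate carboxylase by -0.43 and -0.28. All these shifts were negative. A difference in RNA quality therefore cannot be told apart from the germ-free state in the germ-free comparisons below.

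In the colon, among bright genes whose probe sets all went the same way, the largest increase on the germ-free array was in Fabp6, the ileal bile acid binding protein, at 6008 against 767 (7.83-fold). Slc15a1, the intestinal peptide transporter, was 7.20-fold higher, the NKG2D ligand gene H60c 6.52-fold and Calcb, encoding calcitonin gene-related peptide beta, 6.28-fold. Cyp1a1, a target of the aryl hydrocarbon receptor, was at least 5.92-fold higher. Ptk6 and Adgrd1 were at least 5.49-fold and 5.46-fold higher, followed by Suox (4.72-fold), Ttc36 (3.90-fold) and the amino acid transporter Slc6a20a (3.75-fold). The largest decreases were in Ces2a, a carboxylesterase, at 406 against 8119 (a log2 change of -4.32), and Cyp3a25, at least 19.8-fold lower. The immunoglobulin light chain segment Igkv8-30 was 15.5-fold lower, the sterol transporter Abcg5 at least 13.4-fold, the manganese transporter Slc30a10 13.0-fold and the IgA heavy chain Igha 9.19-fold. Jchain, which joins IgA dimers, was 7.87-fold lower, the calcium-binding protein gene S100g 7.16-fold, the water channel Aqp8 7.14-fold and Vstm5 5.39-fold.

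Genes of nutrient digestion and transport stood higher on the germ-free colon array. Of 20 measured members 5 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.44 log2, above all 10000 random lists. Besides Slc15a1 and Slc6a20a, the peptidase Dpp4 was 3.36-fold and the peptidase Enpep 2.91-fold higher. Absorptive enterocyte markers had 3 of 10 measured members at least 2-fold higher and a median of 0.58, with the apolipoprotein Apoa1 at least 3.93-fold higher. Of the bile acid handling genes 1 of 8 (Fabp6) was at least 2-fold higher, and the median of 0.32 lay at percentile 99.5. Of 14 colonocyte markers 2 were at least 2-fold lower, Aqp8 and Slc37a2 (at least 5.04-fold), with a median of -0.12 at percentile 4.47.

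Xenobiotic metabolism genes included 7 of 35 measured members at least 2-fold lower and 2 at least 2-fold higher on the germ-free colon array, with a median of -0.20 at percentile 0.04. The lower ones included Ces2a, Cyp3a25 and the glutathione transferase Gstt1 (4.40-fold). Cyp1a1 was among the higher ones. In fatty acid synthesis 5 of 15 members were at least 2-fold lower and 0 higher, among them the desaturase Scd1 (3.94-fold) and malic enzyme Me1 (3.95-fold), while the list median of -0.14 lay within the random lists at percentile 9.11. Glycolysis genes had a median of -0.23 (percentile 0.30) with 1 of 14 members, Hk2, at least 2-fold lower (2.15-fold).

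Interferon-stimulated and MHC presentation genes were lower on the germ-free colon array, while other immune lists went either way. Of 23 measured interferon-stimulated genes 8 were at least 2-fold lower and 0 higher, with a median of -0.60, below all random lists. Ifit3 was at 295 against 1097 (3.72-fold lower), Ifit1 3.45-fold lower, Ifit2 at least 3.47-fold lower and Rsad2 3.24-fold lower. Of 7 MHC class II presentation genes 2 were at least 2-fold lower, H2-Ab1 (2.36-fold) and H2-Aa (2.26-fold), with a median of -0.81, below all random lists. Of 12 MHC class I presentation genes 1, H2-Q10, was at least 2-fold lower (2.20-fold), with a median of -0.45 at percentile 0.02. The antimicrobial lectin Reg3g was 3.91-fold lower and Reg4 2.74-fold lower, the only 2 of 9 measured antimicrobial genes past 2-fold, and that list's median of -0.13 lay at percentile 10.7. Epithelial chemokines and cytokines had a median of -0.43 (percentile 0.27) with members on both sides. The cytokine Il18 was 2.75-fold lower, the interleukin 1 receptor antagonist Il1rn 3.75-fold higher and the chemokine Ccl25 2.13-fold higher. Acute phase and complement genes had 2 of 6 members at least 2-fold higher, Saa2 (2.16-fold) and Cfb (2.02-fold), and a median of 0.65 at percentile 99.97.

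Markers of some other cell types were also lower on the germ-free colon array, beside these immune lists. Of 15 cell type lists 5 stood below their random lists and 1, the absorptive enterocyte list, above. The median was -0.98 over 5 plasma and B cell markers (percentile 0.09), -0.78 over 8 endothelial markers (percentile 0.02), -0.46 over 12 fibroblast and smooth muscle markers (percentile 0.17), -0.67 over 4 Paneth cell markers (percentile 0.50) and -0.63 over 8 tuft cell markers (percentile 0.52). Over 6 intraepithelial and T lymphocyte markers it was -0.44 (percentile 4.45) and over 10 myeloid markers -0.36 (percentile 4.80), both within their random lists. So were the goblet (-0.09, percentile 8.90), enteroendocrine (-0.07, percentile 29.2) and crypt stem and progenitor lists (0.01, percentile 56.4). Cd8a was 2.91-fold and the endothelial receptor Kdr 2.80-fold lower. Only 8 of the 19 symbols of the Paneth cell list matched a gene here, so that list rests on few members. Between the wild type arrays 4 of its 5 measured members were at least 2-fold higher in ileum and 1 was lower (log2 -4.07). Its colon median therefore need not reflect Paneth cells.

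Cell cycle and DNA replication genes had a median of 0.49 on the germ-free colon array, above all random lists, with 3 of 33 members at least 2-fold higher and 1 lower. Cdc20 was 2.75-fold higher by its brightest probe set, but had a log2 change of -0.41 once probe sets that can match several transcripts were left out. Uhrf1 was at least 2.19-fold and Mcm6 2.12-fold higher, and Aurkb at least 2.34-fold lower. Of 16 circadian clock output genes 4 were at least 2-fold higher and 0 lower, namely Dbp (3.21-fold), Per2 (at least 3.06-fold), Per1 (2.81-fold) and Cry2 (2.07-fold), while the list median of 0.12 lay at percentile 88.4 and was -0.06 with median scaling. Immediate early genes had a median of -0.38, below all random lists, with 0 of 18 members past 2-fold and Egr1 at 1857 against 3367.

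Of 11746 genes measured in the colon, 152 were at least 2-fold higher and 379 at least 2-fold lower on the germ-free array, 82 of them as bounds. The balance of these counts depended on the scaling between arrays. The genes at least 2-fold higher made up 28.6% of those past 2-fold here, 51.8% in the values as deposited (296 higher, 275 lower) and 19.5% with median scaling (121 higher, 500 lower). The median of all measured genes lay at -0.01 log2 here, 0.09 as deposited and -0.14 with median scaling, and single values should be read against that shift. Of the 32 function lists 14 lay outside the middle 95% of their random lists, against 1.6 for lists drawn at random. Some of the lists above left their side of that range under 1 or more alternatives: the acute phase, bile acid, glycolysis, chemokine, plasma cell, fibroblast, Paneth and tuft cell lists, and the chemokine median turned to 0.10 with a floor at the 75th percentile.

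**Figure D1:**
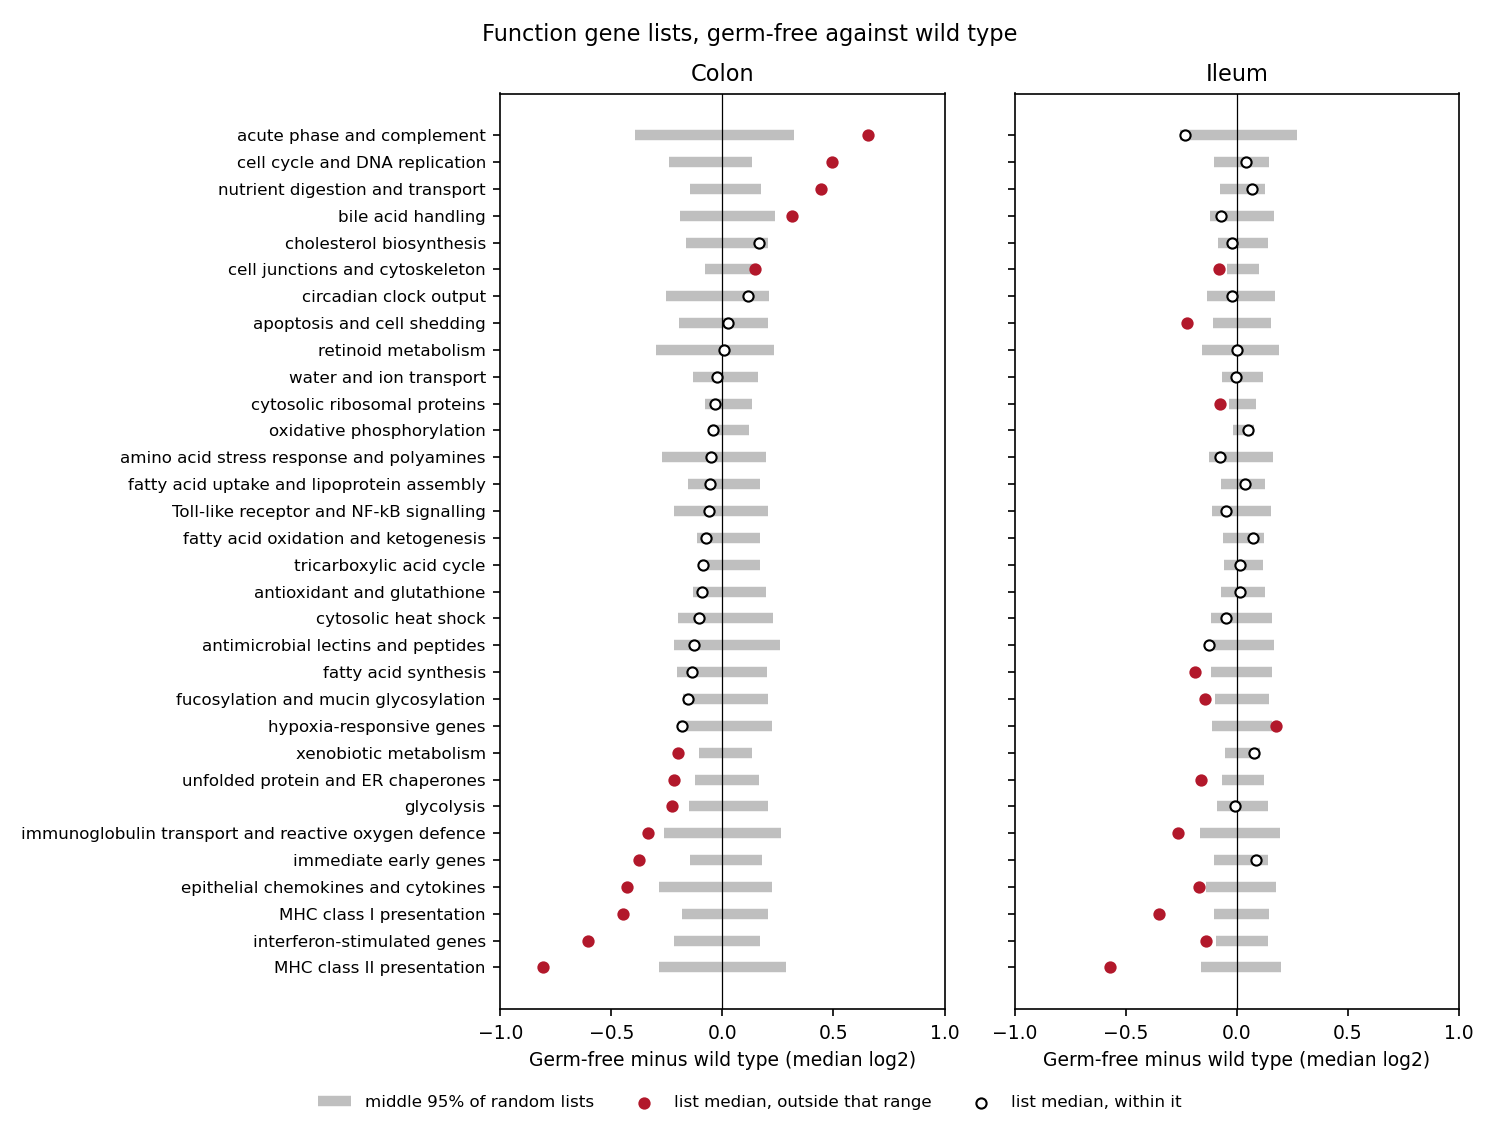
Median log2 change (germ-free minus wild type, horizontal axis) of each of 32 function gene lists in colon (left) and ileum (right), 1 array per group; grey bars span the middle 95% of 10000 random lists matched on expression, filled red points lie outside it and open points within. MHC class II presentation had the lowest median in both panels (-0.81 in colon and -0.57 in ileum), and interferon-stimulated genes lay at -0.60 in colon and -0.14 in ileum.

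In the ileum, the largest increase on the germ-free array by the same criteria was in Cyp1a1, at least 4.52-fold higher. The metallothioneins Mt2 and Mt1, which bind zinc and copper, were 3.80-fold and 2.08-fold higher. Fam151a was 3.37-fold higher, Copg2 3.20-fold, Flvcr2 2.91-fold, Kctd13 2.39-fold and the scramblase family gene Plscr4 2.21-fold. Tes3-ps, a pseudogene, was 2.20-fold and Kctd16 2.16-fold higher. The largest decreases were in Rgs5, a pericyte gene, at 193 against 2632 (13.6-fold), and Fabp4, a fatty acid binding protein of fat and vessel cells (13.5-fold). Il3 was at least 13.4-fold lower, resting on 1 probe set that read 836 on the wild type ileum array and below 4 on each of the other arrays. Myl6b was at least 8.56-fold lower, the amino acid transporter Slc6a14 7.59-fold, Jchain 6.83-fold, Cald1 6.77-fold, Car3 at least 6.28-fold, the acute phase protein Saa1 6.25-fold and Igkv8-30 6.06-fold.

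MHC presentation genes were also lower on the germ-free ileum array. MHC class II presentation had 0 of 8 members past 2-fold and a median of -0.57, below all random lists, with H2-Ab1 at 907 against 1774 and H2-Aa at 942 against 1682. MHC class I presentation had a median of -0.35, also below all random lists, with 1 of 12 members at least 2-fold lower, the immunoproteasome subunit Psmb8 (3.02-fold). Of 24 interferon-stimulated genes 0 were past 2-fold and the median was -0.14 (percentile 0.44), although Rsad2 was higher, at 724 against 412. Immunoglobulin transport and reactive oxygen defence genes had a median of -0.26 (percentile 0.21), with the oxidase subunit Cyba 2.34-fold lower. The same list had a median of -0.33 (percentile 1.04) in the colon, with 0 of 9 members past 2-fold. Of 10 antimicrobial genes 1, the lectin Itln1, was at least 2-fold lower (2.26-fold), and Reg3g read 9632 against 11960. Xenobiotic metabolism had 1 member at least 2-fold higher and 2 lower of 35, with a median of 0.08 at percentile 90.3.

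Markers of some other cell types were lower beside these lists, in part the same as in colon. Of 15 cell type lists 6 stood below their random lists and 0 above. The tuft (percentile 12.85) and endothelial lists, lower in colon, lay within theirs. The goblet list (median -0.12, percentile 1.075) came within its random lists with a floor at the 75th percentile, no floor or the mean of a gene's probe sets. The medians on the germ-free ileum array were -0.37 over 6 plasma and B cell markers (percentile 0.20), -0.35 over 8 intraepithelial and T lymphocyte markers (percentile 0.34), -0.29 over 11 myeloid markers (percentile 0.22) and -0.20 over 17 fibroblast and smooth muscle markers (percentile 0.235). In the last list 4 members were at least 2-fold lower, among them Tagln (at least 3.93-fold), Des (at least 2.33-fold) and Vim (2.31-fold). Paneth cell markers had a median of -0.76 over 5 members, below all random lists, with Lyz1 at 7687 against 10210.

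Of 11750 genes measured in the ileum, 27 were at least 2-fold higher and 82 at least 2-fold lower on the germ-free array, 31 of them as bounds. Together they made up 0.928% of the measured genes, where 0.424% of unchanged genes went past 2-fold on simulated ileum arrays. The simulated noise SD of 0.25 log2 was per array, so a simulated change was noisier than the SD of 0.23 between ileal probe sets. The part of the ileum genes that is noise therefore cannot be read from these shares, and single genes near 2-fold should be read with care. In colon the shares were 4.52% measured and 0.405% simulated. The share of higher genes was 24.8% here, 21.2% as deposited and 25.2% with median scaling. Of the 32 function lists 12 lay outside the middle 95% of their random lists, 1 higher and 11 lower. The intraepithelial lymphocyte list came within its random lists without probe sets that can match several transcripts, and the myeloid and chemokine lists with a floor at the 25th percentile or none. The apoptosis list did so with a floor at the 75th percentile, and the hypoxia, ribosomal protein and cell junction lists with the mean of a gene's probe sets.

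The colon and ileum shared few of the genes past 2-fold. Among 11065 genes measured in both regions, 13 were at least 2-fold lower on both germ-free arrays, where independent lists would share 2.16, and 1 was higher on both (Cyp1a1), where independent lists would share 0.291. The genes lower in both with the largest smaller change were Jchain (log2 -2.98 in colon, -2.77 in ileum), Igkv8-30 (-3.95, -2.60), Igha (-3.20, -2.07), the muscle gene Tpm2 (-1.81, -1.79), S100g (-2.84, -1.77), lipoprotein lipase Lpl (-1.86, -1.76), Ces2a (-4.32, -1.39) and the granzyme Gzma (at least -1.30, -1.62). After Cyp1a1, the genes higher on both by the same measure were Mt2 (0.93, 1.92), the lipoprotein lipase inhibitor Angptl4 (1.20, 0.91), Tmem267 (1.29, 0.83), Spsb4 (at least 1.48, 0.72), Apoh (at least 1.19, 0.70), Acy1 (at least 0.93, 0.70) and Sco2 (0.86, 0.69). Across all these genes, which are not independent replicates, the changes in colon and ileum correlated at r = 0.0831 (Spearman's rho = 0.0608), and at r = 0.162 (rho = 0.139) across the 7497 of them above the pooled 75th percentile on at least 1 array. Some colon lists had smaller values in the ileum. The list median of the difference between the colon and the ileum change was -0.61 for interferon-stimulated genes and -0.26 for xenobiotic metabolism, and 0.55 for nutrient digestion and 0.52 for the cell cycle. It was -0.34 for MHC class II presentation (percentile 1.975), -0.03 for MHC class I presentation (percentile 37.0) and 0.71 for acute phase and complement genes (percentile 99.84). Of the 32 function lists 10 lay outside the middle 95% of their random lists by this measure. The interferon list lay below and the nutrient and cell cycle lists above all random lists, and xenobiotic metabolism at percentile 0.04, which describes these arrays and is no test of the regions. These medians of differences were added after the data were seen.

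**Figure D2:**
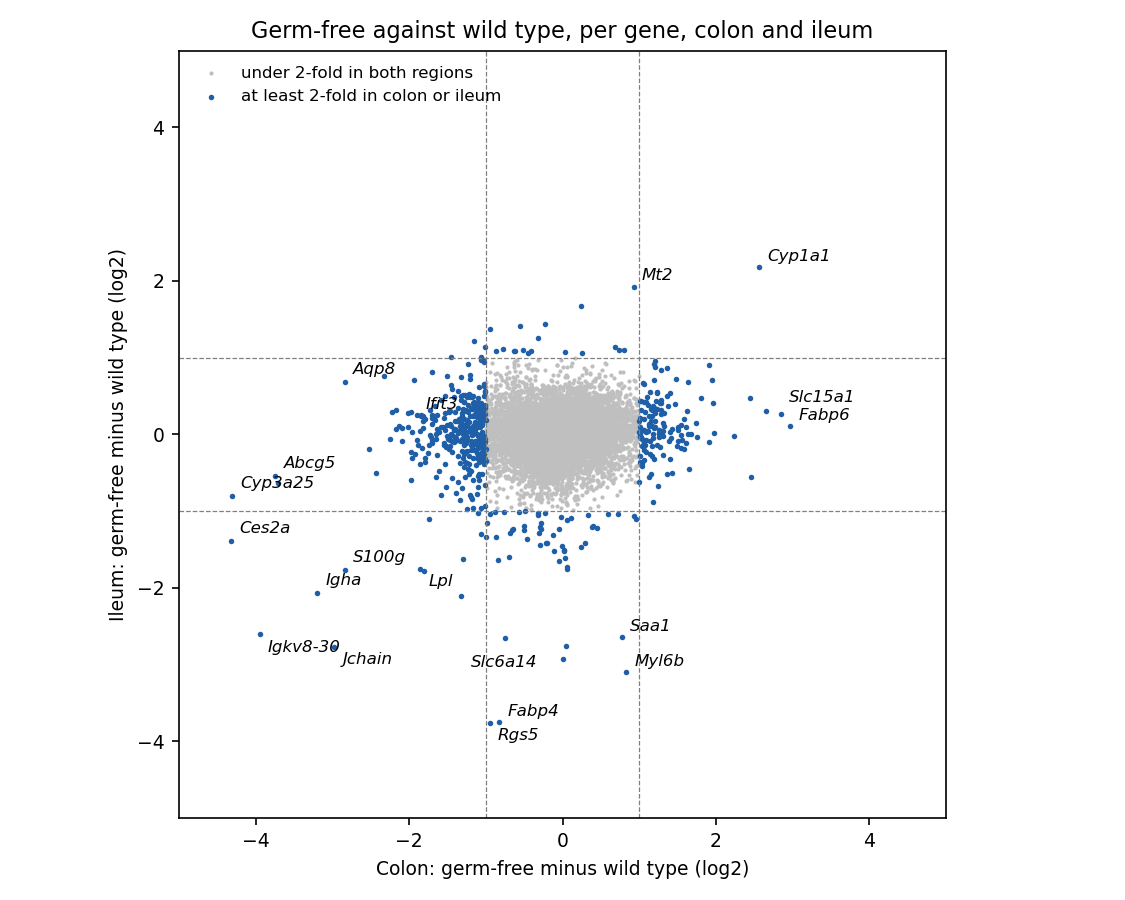
Each point is 1 of 11065 genes measured in both regions, with its log2 change (germ-free minus wild type) in colon on the horizontal and in ileum on the vertical axis; dashed lines mark 2-fold and blue points lie past it in at least 1 region, with values at the floor drawn at their bound. Jchain, Igha and Igkv8-30 lie at the lower left and Cyp1a1 at the upper right, while Fabp6 (2.97, 0.10) and Rgs5 (-0.95, -3.77) were far from 0 in 1 region.

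The regional comparison showed the expression of ileum and colon genes on the arrays so labelled. On the wild type arrays the apolipoprotein Apoa1 was at least 257-fold higher in ileum than in colon, Clca4b at least 107-fold, the anion exchanger Slc26a6 at least 91.2-fold and the amino acid transporter Slc6a19 62.9-fold. Bcl2l15 was at least 65.0-fold and the lectin Itln1 at least 61.6-fold higher. Carbonic anhydrase Car1 was 222-fold lower in ileum, Sptssb at least 92.6-fold, Foxd2 at least 67.7-fold, St6galnac6 67.6-fold, Car2 at least 60.4-fold and Sult1a1 at least 52.5-fold. On the germ-free arrays Apoa1 was 66.4-fold and the lysozyme Lyz1 58.7-fold higher in ileum, and Car1 at least 199-fold, Saa1 72.7-fold and Slc6a14 56.9-fold lower.

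Of 12000 genes measured in wild type, 725 were at least 2-fold higher and 712 lower in ileum, and of 11986 in germ-free, 883 were higher and 705 lower. In germ-free the higher share was 55.6% here, 38.5% as deposited and 64.5% with median scaling, with a median of all genes of 0.04, -0.11 and 0.18. Among 11555 genes measured in both, 431 were higher and 463 lower in ileum in both states, where independent lists would share 54.4 and 42.5, and 6 were past 2-fold in opposite directions. The changes between regions correlated at r = 0.786 across genes (rho = 0.602). Cholesterol biosynthesis genes were at least 2-fold higher in ileum for 11 of 17 members in wild type (median 1.45) and 10 of 17 in germ-free (median 1.24). Fatty acid uptake and lipoprotein assembly genes were higher for 14 of 23 and 15 of 23 members. Nutrient digestion genes had 18 of 23 members at least 2-fold higher in ileum in wild type (median 2.47) and 18 of 24 in germ-free (median 1.998). Interferon-stimulated genes were at least 2-fold lower in ileum for 8 of 24 members in wild type (median -0.60) and 2 of 23 in germ-free (median -0.06, or 0.10 with median scaling), and colonocyte markers for 7 of 14 (median -1.43) and 5 of 14 (median -0.37). The wild type colon array enters both the wild type regional comparison and the colon germ-free comparison, so their interferon results are not independent of each other.

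**Figure D3:**
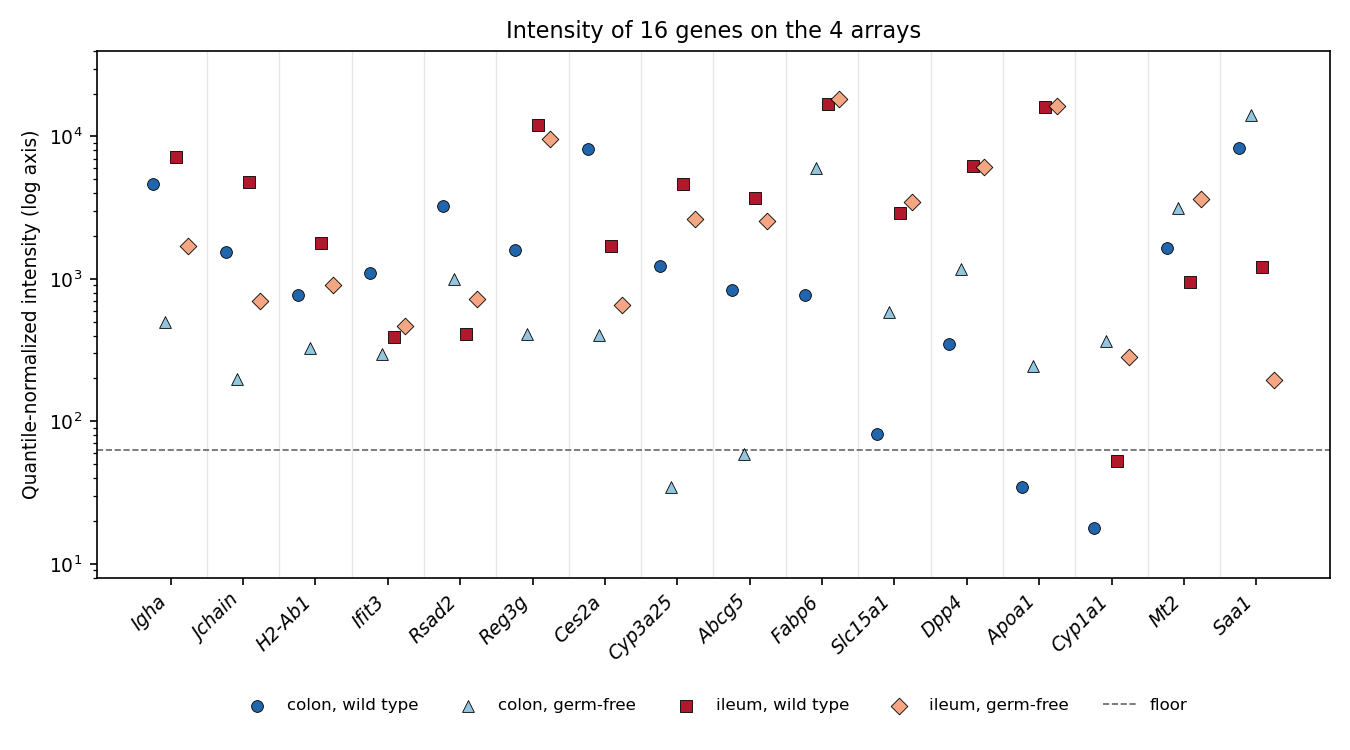
Quantile-normalized intensity (log axis) of 16 genes on the 4 arrays, 1 point per array, with the floor of 62.4 as a dashed line. Igha, Jchain and H2-Ab1 were lower on the germ-free array of each region, Ifit3 was at 1097 on the wild type colon array and between 295 and 468 on the others, and Fabp6 read 767 and 6008 in colon.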

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

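Every test in this part was chosen only after the result was seen, except array scaling for the ileal genes and the probe set noise behind the colon and ileum counts.

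Genes past 2-fold in opposite directions in colon and ileum stood out because the pair of arrays in each region went the other way, and the differences between the regions were not tested. There were 4, named here after their values were seen, where independent lists would give 1.59. Of the 4, 1 stayed past 2-fold both ways in the values as deposited and 2 with median scaling. The log2 change from wild type to germ-free was -1.15 in colon and 1.22 in ileum for 9030619P08Rik, -1.46 and 1.01 for the acetylcholine receptor subunit Chrna3, -1.06 and 1.01 for the ubiquitin ligase Rnf144b, and -1.01 and 1.13 for the pseudogene Tes3-ps. The cell junction and cytoskeleton list stood above its random lists in colon (median 0.15) and below them in ileum (-0.08), also untested, and the colon median was -0.12 with median scaling.

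Probe sets with no gene symbol or several stayed out of the comparisons. Of those measured, 140 of 4082 were at least 2-fold higher on the germ-free array in colon and 93 lower, and 17 of 3880 were higher in ileum and 17 lower.

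Of 150 measured ileum-enriched genes, at least 4-fold higher in the mean of both ileum arrays than of both colon arrays, 26 were at least 2-fold higher on the germ-free colon array, among them Fabp6, Slc15a1, Dpp4 and Enpep, and 9 at least 2-fold lower, with a median of 0.24 log2. Of 162 colon-enriched genes 8 were higher and 21 lower, with a median of -0.18. Ileal epithelium mixed into that sample is argued against as the source of the whole pattern. For the 22 genes abundant in ileum and silent in wild type colon, the increase over wild type colon was taken as a share of the distance to their ileal level. Its median was 0.618%, and 13 of the 22 stayed at or below the floor on the germ-free colon array. By the same measure the 26 genes of the pattern, chosen for being at least 2-fold higher, needed a median of 17.99%. Apoa1, Apoc3 and Myrfl were in both sets. A small admixture stays open, as Apoa1, 1 of the 26, needed only 1.304%. Scaling is argued against too, since 92.3% of the 26 stayed at least 2-fold higher under the scaling least favourable to them. The position along the colon from which cells were captured, the staining that the labels mention only for germ-free samples, and the absence of microbes stay open and untested, and the last may be the biological explanation.

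Igha, Jchain and Igkv8-30 were lower on both germ-free arrays, with log2 changes of -2.07 or lower. In colon, less connective tissue in the capture is argued against as the whole explanation. The lowest of 7 bright markers of fibroblasts and smooth muscle was -0.73 and their median -0.509, where the smallest immunoglobulin change was -2.98. Some loss of connective tissue stays open. In that list 8 of 12 measured markers were below 0 (percentile 0.17), and the muscle gene Tpm2, outside it, fell by more than any of the 7. Less vessel cannot be told apart in colon, where none of 8 measured endothelial markers (median -0.778) was bright enough to show such a decrease. In ileum, 9 connective tissue and endothelial markers had a median of -0.374, but Fabp4 at -3.75, too weak to serve in colon, keeps less connective tissue and vessel open. In ileum, 6 T cell and myeloid markers had a median of -0.616 (lowest -1.62 for Gzma), with 5 of the 6 below 0. None was as low as the smallest immunoglobulin change of -2.07. An equal loss of all immune cells is therefore argued against as the whole explanation there, while a smaller general loss stays open. In colon this cannot be told apart, since only Csf1r was bright enough (-0.224). Fewer plasma cells without microbes is a candidate explanation that these arrays did not test. The plasma and B cell list, which holds Jchain, had 2 of 5 measured members at least 2-fold lower in colon (median -0.98). In ileum Jchain was the only 1 of 6 past 2-fold (median -0.37). Whether the other members were bright enough to show the immunoglobulin decrease was not examined.

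More genes were at least 2-fold apart in colon (531) than in ileum (109). Array scaling is argued against, since the ratio of the counts was 4.87 here, 5.49 in the values as deposited and 6.03 with median scaling. Independent probe set noise alone is argued against. The covariance of the change between 2 bright probe sets of a gene was 2.46 times as large in colon as in ileum. Its 95% bootstrap interval, 1.67 to 3.71 over 2647 genes, resampled genes and says nothing of the spread between arrays or mice. Such noise was also larger in colon (SD between probe sets 0.30 against 0.23 in ileum), so its part in the counts stays open. A larger difference in RNA integrity cannot be told apart. The mean size of the 5' to 3' shift of the Actb, Gapdh and pyruvate carboxylase controls was 0.343 in colon and 0.862 in ileum, but that of pyruvate carboxylase alone (0.43 and 0.28) and the decrease of 18S ribosomal RNA (-1.23 and -0.93) were larger in colon. An artifact of a whole array pair, which could move probe sets of a gene together, and a larger effect of microbes in colon stay open, with 1 array per group.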

How the results depend on the processing

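All alternatives here were chosen before the values were seen. Each group had 1 array, so there were no replicates to leave out or pair by number. A fit over all 4 arrays with the region as a block was left out. Over 122 alternative values of the counts and the correlation, 65 moved little (counts by under 1.5 times) and 57 moved further. A count could not reverse by these rules, and the correlation kept its sign. The balance of the colon counts did turn in the values as deposited, with 296 genes higher and 275 lower. The number of function lists apart from random lists stayed between 11 and 15 in colon and between 10 and 13 in ileum, and the correlation between 0.02 and 0.18. A value counts as reversed where a list outside its random lists, or a gene past 2-fold, changed sign. Of 1286 alternative list medians 284 moved by at least the SD of their random lists and 2 reversed. Of 10670 alternative values of named genes 905 moved by at least the SD between probe sets and 4 reversed. Lists within their random lists could change sign without being counted, as the circadian list in colon (-0.06) and, between regions in germ-free, the interferon (0.10) and fatty acid oxidation lists (0.013) did with median scaling.

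The floor sets how many weak genes count, since signal over background limits what can be called. With a floor at the 25th percentile, 409 genes were higher and 768 lower in germ-free colon, 145 higher and 233 lower in germ-free ileum, 8 higher and 30 lower in both and 33 opposite, and 1375 higher in ileum in germ-free. With a floor at the 75th percentile these were 50 and 136, 5 and 22, 0 and 5, and 0 opposite, with 427 higher and 395 lower in ileum in wild type and 419 and 384 in germ-free. With no floor and 16 added, they were 323 and 586 in colon, 118 and 174 in ileum, 12 and 21 in both and 21 opposite. More or fewer genes near background enter by construction.

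At 1.5-fold the counts were by construction larger: 727 higher and 1273 lower in colon, 282 and 372 in ileum, 33 and 63 in both, 85 opposite, and 1627 and 1662 between regions in wild type and 2061 and 1604 in germ-free. At 3-fold they were 27 and 76 in colon, 4 and 24 in ileum, 6 lower in both, 0 opposite, 318 and 313 in wild type and 301 and 272 in germ-free. With the mean of a gene's probe sets they were 87 and 189 in colon, 15 and 49 in ileum, 8 lower in both, 2 opposite and 585 higher in germ-free ileum than colon. As deposited, 296 were higher in colon, 2 higher in both and 2 opposite. The cause was not tested for the probe set mean and the deposited values. Median scaling and leaving out probe sets ending in _s_at or _x_at moved no count past 1.5 times.

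The reversed values were these, and the cause was not tested. With median scaling, the cell junction list had a colon median of -0.12. With a floor at the 75th percentile the chemokine list had a colon median of 0.10. Without probe sets ending in _s_at or _x_at, Cdc20 had a colon change of -0.41, Ang4 a change of -0.015 between ileum and colon in germ-free, and Gpt2 changes of 0.43 in germ-free and 0.038 in wild type.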

Other observations

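No explanation was tested in this part, and every value here was chosen after the results were seen, within the lists fixed beforehand.

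Genes of vitamin A metabolism went both ways on the germ-free colon array. Cyp26b1, which degrades retinoic acid, was at least 4.25-fold lower and the alcohol dehydrogenase Adh1 3.37-fold lower, while Lrat, which esterifies retinol, was higher by a log2 change of 1.58 and the retinol transporter Stra6 at least 2.24-fold higher. Lipid uptake genes also went both ways, with 3 of 22 members at least 2-fold higher and 3 lower in colon. Apoc3 was at least 3.09-fold higher, and the lipoprotein receptor Scarb1 and the lipase Pnliprp2 were 3.21-fold and 3.17-fold lower. The tuft cell genes Dclk1 and Trpm5 were 2.30-fold and 2.06-fold lower in colon, and the receptor Tlr4 was 2.27-fold higher. The small heat shock gene Hspb1 was 2.99-fold lower and the pyroptosis family gene Gsdmc2 3.06-fold lower in colon, where the caspase Casp4 was 2.05-fold higher.

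Endoplasmic reticulum chaperone genes were slightly lower on both germ-free arrays, with 0 of 24 members past 2-fold. Their median was -0.22 in colon (percentile 0.10) and -0.16 in ileum (percentile 0.03), with Herpud1 at -0.66 and Pdia4 at -0.62 in colon and Pdia6 at -0.64 in ileum. Markers of plasma and B cells, of which plasma cells are rich in these chaperones, were lower on the same arrays (median -0.98 and -0.37), and how far the lists move together was not tested. In ileum, apoptosis genes had a median of -0.22 (percentile 0.03), fatty acid synthesis genes -0.19 (percentile 0.31), glycosylation genes -0.14 (percentile 0.55) and ribosomal protein genes -0.07 (percentile 0.25), and hypoxia-responsive genes 0.17 (percentile 98.6). The apoptosis list came within its random lists with a floor at the 75th percentile (median -0.007), and the hypoxia list (0.03) and the ribosomal protein list (-0.08) with the mean of a gene's probe sets. The sialyltransferase St3gal4 was 2.33-fold and the peptide-processing enzyme Cpe 3.05-fold lower on the germ-free ileum array.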
